A study of Mus musculus with 22 samples.

How the data were processed

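RNA was measured by Smart-seq in 22 libraries of mouse CD4+ T cells. Per the labels' protocols, CD4+ T cells from lymph nodes of scurfy mice received a vector with human FOXP3 or an empty vector with the LNGFR reporter. Recipients were 10-day-old scurfy mice given cyclophosphamide at 50 mg/kg, cells were injected on day 14, and human IL-2 followed at 1000 IU per g, daily for 5 days and then weekly. On day 50, 1000 LNGFR+ or CD45.1 cells were sorted from lymph nodes in 2 rounds for each library. Polyadenylated RNA was reverse transcribed, fragmented with Tn5 transposase, amplified by 18 cycles of PCR and sequenced in pairs of 38 bp reads. Such reads carry no molecular identifiers, so PCR copies are counted with the molecules they came from, and intervals and floors cover counting error only.

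The deposited table holds raw read counts per gene symbol, 1 column per library, which the authors did not normalize as far as the values show. Per the submitters' processing notes, STAR 2.7.3a, featureCounts and Subread 2.0.0 were used with mm10 (GRCm38). The gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Genes that overlap, or that share sequence with a copy, can therefore hold each other's reads. The table lists 55011 genes, of which 46911 had at least 1 count and 52830 matched 1 gene of GENCODE M21 by symbol, as did 15151 of the 15462 tested. Positions are those of GENCODE M21 on GRCm38. The table has no row that names the vector, and the human transgene was not analysed here.

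Groups were taken from the titles. The 2 libraries of a code were compared first. Their log2 CPM correlated at 0.96 to 0.98 across genes except in G1 (0.45) and E2 (0.80), and a chi-square of their counts per degree of freedom was 2.92 to 85.1, so no pair agreed within sampling noise. The 2 were summed as 1 replicate, because the labels do not say that they come from separate animals. Library totals ran from 332570 to 5453375 counts, and from 2204508 without the 3 weak libraries. A gene at 0 in a group was given a floor of 3 counts over the group, and 1 to 3 counts a 95% exact interval of the ratio.

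The main test, fixed with the gene lists and alternatives before the data were examined, was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM normalization, filterByExpr) on all 3 groups in 1 fit, with Benjamini-Hochberg adjusted p under 0.05. CPM are counts per 1e6 of the TMM-scaled library, given as mean and SD over codes. The SE of a log2 fold change is its absolute value divided by the square root of the test's F statistic. It approximates a standard error and is least reliable where a group has few counts. The common biological coefficient of variation was 0.491. In a test on simulated data made from the real means, library sizes and dispersions of 15462 genes, with 200 changed genes per comparison, 53.7% of genes changed 4-fold were recovered for FOXP3 against LNGFR, 23.9% for WT Treg against LNGFR and 46.3% for FOXP3 against WT Treg. For genes changed 2-fold the shares were 5.97%, 2.99% and 4.48%, and for 8-fold 77.3%, 54.5% and 78.8%. False calls made up 4.21%, 1.82% and 5.49% of all calls.

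Of 28 fixed gene lists with 398 entries, the text describes those of genes higher and lower in Treg, effector cytokines, T helper 2, type 1 and cytotoxic, follicular helper, trafficking, cell-cycle, stress, glycolysis, respiration, B-cell and plasma-cell genes. Which of the 28 lists are described was chosen after their values and their dependence on the settings had been seen, in part to keep the account short, so the choice is not independent of the results. Lists share members, such as Il4 and Il5. Each was tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Mean log2 CPM per code was compared by exact two-sided permutation tests, which cannot go below 0.0179 for 5 against 3 codes or 0.1 for 3 against 3. Named genes were Foxp3 and Ngfr, the 8 largest changes per direction and comparison among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap of codes (without gene models and antigen receptor segments), and up to 6 members of the 2 Treg lists and 4 of other described lists by smallest p. No members of the glycolysis and respiration lists and only called members of the B-cell and plasma-cell lists were named. Cd79a, Mki67, Il2ra, the sex-linked genes, and those near Ptprc were chosen after their values were seen.

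Overlap between FOXP3 and WT Treg calls was set against sets of counts drawn with the fitted dispersion and the real library sizes. Each gene was drawn independently, so deviations shared by many genes of a code are not in these sets. In some all 3 groups were unchanged. In others, added after seeing the data, FOXP3 was drawn at the LNGFR mean, the called genes of WT Treg at their own means, and every other gene at its mean over all codes.

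The 32 alternative settings, 4 of them added after seeing the data, were other size factors, DESeq2 1.42.0, other filters, only the 2 groups compared, each library as a replicate with and without a replicate block, limma voom with the code as a random effect or with quality weights, the libraries numbered 1 or 2 alone, the FOXP3 codes that start with F or with N alone, a minimum log2 fold change of 1, and leaving out each code. Added after seeing the data were the fits without the 3 weak libraries, without codes E2, G1 and N3, with each code's trend with exon length removed, and with no scaling beyond the library total. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.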

Results

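The transcriptomes of 3 kinds of CD4+ T cell were compared at day 50 of an adoptive transfer experiment in scurfy mice, which lack functional Foxp3 and develop fatal autoimmunity. In the FOXP3 group, scurfy CD4+ T cells had received a vector with human FOXP3 and the cell-surface reporter LNGFR, a truncated nerve growth factor receptor. In the LNGFR group, such cells had received the reporter alone. In the WT Treg group, the transferred cells were CD4+CD25+ regulatory T cells (Treg) that carried the CD45.1 allele. Each of the 22 libraries was made from 1000 cells sorted from lymph nodes. Titles carry a code such as F1 or G2, and 2 libraries share each code, so the 2 were summed and each code was counted as 1 replicate, which left 5 FOXP3 codes, 3 LNGFR codes and 3 WT Treg codes. The labels do not say whether a code is a mouse, so p-values measure the spread between these codes, part of which may be technical.

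Library totals ran from 332570 to 5453375 gene counts. Summed per code, the 5 FOXP3 codes held 8344444 to 10376164 counts, LNGFR 3109515 in G1, 5867295 in G2 and 7881352 in G3, and WT Treg 1154626 in E2, 5946290 in G4 and 7088371 in L1. The weak libraries were both of E2 (641980 and 512646 counts) and the second of G1 (332570 counts). In these 3 libraries 58.2%, 49.5% and 28.9% of all counts fell on the Gm10800 family of repeat-derived gene models, against 2.19% to 4.47% elsewhere. B-cell genes were abundant in both libraries of FOXP3 code N3, where the 12 genes of the B-cell list summed to 11500 and 12399 CPM (counts scaled to 1e6 per library), and in the first library of LNGFR code G1 with 8180 CPM. The other libraries held 1089 to 4077 CPM. In WT Treg codes G4 and L1 most of the sum was Ighm (3473 and 3041 CPM, TMM-scaled per code). Cd79a was only 37.2 and 15.85 CPM there and Ms4a1 24.1 and 13.98 CPM, so the sum does not follow these B-cell markers. Every comparison was therefore also computed without the 3 weak libraries and without codes E2, G1 and N3, which leaves 4, 2 and 2 codes; both choices were made after seeing the data.

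**Figure D1:**
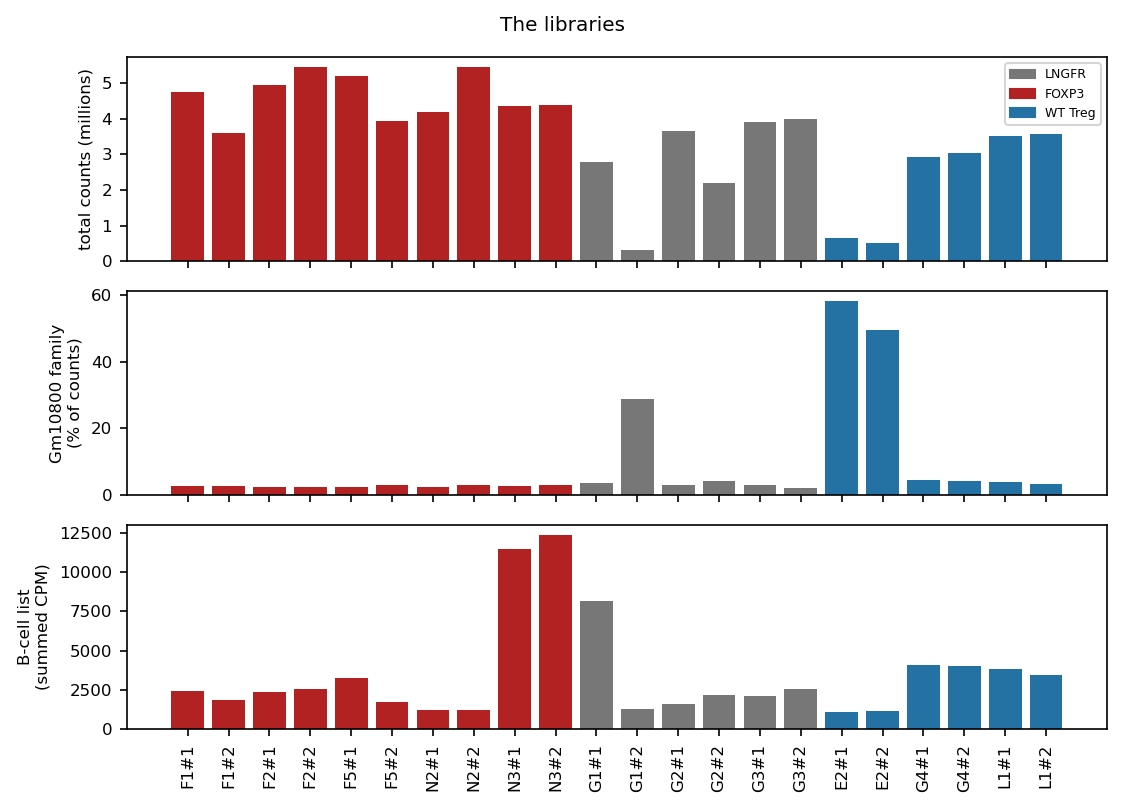
Total gene counts (axis in units of 1e6), percentage of counts on the Gm10800 family and summed CPM of the B-cell list in each of the 22 libraries, with bars coloured by group. The 2 libraries of E2 and the second of G1 have the lowest totals and the highest Gm10800 shares (28.9% to 58.2%), and the 2 libraries of N3 have the highest B-cell sums (11500 and 12399 CPM). In WT Treg codes G4 and L1 most of the B-cell sum is Ighm, and Cd79a is low (37.2 and 15.85 CPM).

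Foxp3, the transcription factor that defines Treg and the gene disabled in scurfy, was read through the mouse gene (ENSMUSG00000039521.13, GRCm38 chromosome X, 7573644 to 7595245). It stood at 1305 ± 521 CPM in WT Treg (SD, n = 3), 228 ± 54.3 CPM in FOXP3 (n = 5) and 86.1 ± 51.5 CPM in LNGFR (n = 3). The log2 fold change was 3.92 ± 0.52 (SE) for WT Treg against LNGFR (edgeR adjusted p = 0.00191) and -2.52 ± 0.40 for FOXP3 against WT Treg (adjusted p = 0.0192). Between FOXP3 and LNGFR it was 1.40 ± 0.43 and missed the threshold (adjusted p = 0.21), although all 5 FOXP3 codes lay above all 3 LNGFR codes. Without codes E2, G1 and N3 that Foxp3 difference was 1.18 ± 0.26 (adjusted p = 0.0185). The vector holds the human gene, and whether its transcripts were counted at mouse Foxp3 could not be read from the table. Mouse Ngfr was not tested. It had 10 counts (30.1 CPM) in the second library of G1, 5.98 and 3.66 CPM in the libraries of N3 and at most 1.56 CPM in the others.

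The first comparison, FOXP3 against LNGFR, asks what differed between scurfy CD4+ T cells with the FOXP3 vector and those with the reporter alone. All LNGFR codes start with G and all FOXP3 codes with F or N, and the labels do not say what the letters mark. WT Treg code G4 also starts with G, while E2 and L1 do not. In FOXP3 against LNGFR the vector cannot be told apart from whatever the letters mark. Type 2 cytokine transcripts fell. Il5, the eosinophil growth factor (GRCm38 chromosome 11, 53720794 to 53725106), averaged 131 ± 73.9 CPM over 3 LNGFR codes and 0.0885 ± 0.122 CPM over 5 FOXP3 codes, where 4 counts were found in all (adjusted p = 3.91e-05). Il13 went from 11.2 ± 4.19 to 0.192 ± 0.232 CPM (adjusted p = 0.0128), and Il4 from 113 ± 18.0 to 34.0 ± 10.1 CPM, a log2 fold change of -1.73 ± 0.31 (adjusted p = 0.0301). Tnfrsf9, the costimulatory receptor 4-1BB, rose from 17.0 ± 6.77 to 162 ± 55.2 CPM, a log2 fold change of 3.23 ± 0.55 (adjusted p = 0.0187). The gut homing receptor Gpr15 rose by 3.52 ± 0.54 on the log2 scale (adjusted p = 0.0116).

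Of 34 genes known to be higher in Treg than in conventional T cells, 2 rose and none fell over all genes tested, and 11 rose and 1 fell when p was adjusted over the list alone. The 2 were Tnfrsf9 and Dusp4, a phosphatase of MAP kinases (5.88 ± 2.20 to 39.5 ± 19.2 CPM, adjusted p = 0.0442). Gpr83 had a log2 fold change of 1.88 ± 0.40 (adjusted p = 0.0594), and Lrrc32, which anchors latent TGF-beta on Treg, 1.94 ± 0.44 (adjusted p = 0.0784). Ikzf2, which encodes Helios, had 1.47 ± 0.37 (adjusted p = 0.109). All 3 lay higher in every FOXP3 code than in every LNGFR code. The list had a median of 0.75, with 29 of 34 members above 0 (camera adjusted p = 2.48e-09; adjusted p = 0.253 with an estimated correlation). Its mean log2 CPM per code was 7.61 ± 0.24 (n = 5) against 6.78 ± 0.14 (n = 3). The exact two-sided permutation p was 0.0179, the smallest that 56 splits allow, and 0.0871 after adjustment over 39 such tests. None of the 39, which cover the described lists in all 3 comparisons, passed after adjustment. In the fit without the 3 weak libraries 8 members rose and 1 fell (adjusted p = 0.0925 with an estimated correlation), and without codes E2, G1 and N3, 18 rose and 2 fell (camera adjusted p = 1.49e-13; adjusted p = 0.0294 with an estimated correlation).

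Of 11 tested genes known to be lower in Treg, 3 fell and none rose, against 5 that fell and 1 that rose adjusted over the list alone. Tnfsf8, the CD30 ligand (chromosome 4, 63831308 to 63861347), fell by 2.10 on the log2 scale (SE 0.25, adjusted p = 0.00181), from 297 ± 38.9 to 69.4 ± 13.4 CPM. Cd40lg, the CD40 ligand, fell from 77.9 ± 19.0 to 30.5 ± 5.43 CPM (adjusted p = 0.0293), and Igfbp4 from 27.4 ± 23.5 to 2.44 ± 1.63 CPM (adjusted p = 0.0418). The list median was -1.35 (camera adjusted p = 1.94e-08; adjusted p = 0.0321 with an estimated correlation).

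Among the effector lists, which share members, 4 of 10 tested effector cytokine genes fell, and 8 adjusted over the list alone, with a median of -1.45 (camera adjusted p = 1.22e-16; adjusted p = 0.000511 with an estimated correlation). The 4 were Il5, Il13, Il4 and Cd40lg. Of 11 tested T helper 2 genes 4 fell, and 5 fell and 1 rose adjusted over the list alone; Il5, Il13 and Il4 were joined by Areg, the growth factor amphiregulin (171 ± 67.9 to 42.5 ± 20.2 CPM, adjusted p = 0.0442). That list's median was -0.54 (camera adjusted p = 2.48e-09; adjusted p = 0.00232 with an estimated correlation). Among 11 tested genes of follicular helper T cells, 3 fell, and 5 fell and 1 rose adjusted over the list alone (camera adjusted p = 4.43e-05; adjusted p = 0.0213 with an estimated correlation). That last value did not hold without the 3 weak libraries (adjusted p = 0.0625 with an estimated correlation) or without codes E2, G1 and N3 (adjusted p = 0.245). The 3 were Tox2 (32.4 ± 11.8 to 9.84 ± 1.19 CPM, adjusted p = 0.0178), Il4 and Sostdc1, which had 66 counts over LNGFR and none over FOXP3, at least 68.8-fold lower against a floor of 3 counts over the group. Of 12 tested stress and immediate early genes 1 fell, and 1 adjusted over the list alone (camera adjusted p = 0.00069; adjusted p = 0.268 with an estimated correlation). It was Ier3, from 89.2 ± 55.5 to 8.96 ± 3.31 CPM (adjusted p = 0.00577). Ccl24, an eosinophil attractant, fell from 15.6 ± 9.60 to 0.174 ± 0.164 CPM (adjusted p = 0.00246). Ramp1, a subunit of the receptor for the neuropeptide CGRP, fell by 4.60 on the log2 scale (SE 0.50, adjusted p = 0.00157).

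All 25 cell-cycle genes had fold changes above 0 with a median of 1.55, while 1 passed over all genes and 17 adjusted over the list alone (camera adjusted p = 3.09e-19; adjusted p = 0.192 with an estimated correlation). That one was Bub1, a spindle checkpoint kinase, at 27.4 ± 13.6 against 4.83 ± 2.22 CPM (adjusted p = 0.0465). Aurkb stood at 80.4 ± 37.4 against 16.6 ± 4.06 CPM (adjusted p = 0.075). The list's mean log2 CPM per code was 6.85 ± 0.88 against 5.26 ± 0.25 (exact permutation p = 0.0714, adjusted p = 0.195). Code N3, the code with the most B-cell RNA, stood apart in this list: its mean log2 CPM was 5.33, and the other FOXP3 codes had 6.98 to 7.51. Of the 25, 5 rose without the 3 weak libraries (adjusted p = 0.183 with an estimated correlation), and without codes E2, G1 and N3, 24 rose (adjusted p = 0.0323 with an estimated correlation); N3 was in part picked for its low cell-cycle level, so that count is not independent of the choice. Of 21 trafficking genes 1 rose, Gpr15, and 4 adjusted over the list alone (camera adjusted p = 0.00112; adjusted p = 0.268 with an estimated correlation). Without the 3 weak libraries 3 rose (adjusted p = 0.183 with an estimated correlation). Without codes E2, G1 and N3, 5 rose and 1 fell (adjusted p = 0.0294 with an estimated correlation). Of 17 tested type 1 and cytotoxic genes none passed, and 1 fell adjusted over the list alone (camera adjusted p = 0.75). Ifng stood at 8.82 ± 5.13 CPM in FOXP3 and 26.1 ± 16.5 CPM in LNGFR (adjusted p = 0.264).

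RNA of other lymphocytes also differed between the codes. Cd79a, a subunit of the B-cell receptor, stood at 994 CPM in N3 and 24.0 to 102 CPM in the other FOXP3 codes, and at 560 CPM in G1 against 107 CPM in G2 and 99.3 CPM in G3. None of the 12 B-cell genes passed, and 1 rose adjusted over the list alone (list median 1.19, camera adjusted p = 0.687). The B-cell median was -0.62 without codes E2, G1 and N3 (camera adjusted p = 0.463), and also negative without N3 alone. All 6 tested plasma-cell genes had fold changes below 0 and none passed over all genes or adjusted over the list alone (median -1.56, camera adjusted p = 0.00671, and 0.268 with an estimated correlation). None passed over all genes without the 3 weak libraries. Without codes E2, G1 and N3, 2 of 5 tested fell over all genes (median -2.99, camera adjusted p = 0.000534, and 0.143 with an estimated correlation). That list summed to 3128 and 4416 CPM in the libraries of G3 and 2190 CPM in the first of G1.

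In all, edgeR's quasi-likelihood test called 26 genes higher and 58 lower in FOXP3 than in LNGFR among 15462 tested, and 1595 genes had an unadjusted p under 0.05. Other large changes were Nhsl2 (log2 fold change 4.58 ± 0.66), Matn2 (2.83 ± 0.34), Popdc2 (2.50 ± 0.46) and Sh3bp4 (2.45 ± 0.33) upward and Gcnt2 (-5.36 ± 0.88), Cxcl3 (-5.01 ± 0.79), Aqp9 (-4.83 ± 0.79) and Slc7a8 (-6.93 ± 1.16) downward. Without the 3 weak libraries the counts were 101 and 149, and without codes E2, G1 and N3 they were 971 and 594, among which 82 of the 84 calls were kept with their sign. The counts depended on single codes: they ran from 1 (without G2) to 161 (without N3) higher and from 12 (without G3) to 152 (without E2) lower. Of 24 named genes called in this comparison, 19 lost the call without at least 1 code of the 2 groups. None changed sign, which their selection from these same codes makes likely by itself. The fold was over 1.5 times smaller for Igfbp4 without G2 (-2.53, adjusted p = 0.391), Cxcl3 without G1 (-4.37, adjusted p = 0.057) and Ramp1 without G1 (-3.69, adjusted p = 0.00135). It was over 1.5 times larger for Ccl24 (-6.98), Gcnt2 (-6.06) and Slc7a8 (-8.16) without N3 and for Il13 without F5 (-6.52), all still called. DESeq2 called 223 higher and 187 lower, and limma with quality weights per code 517 and 516.

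**Figure D2:**
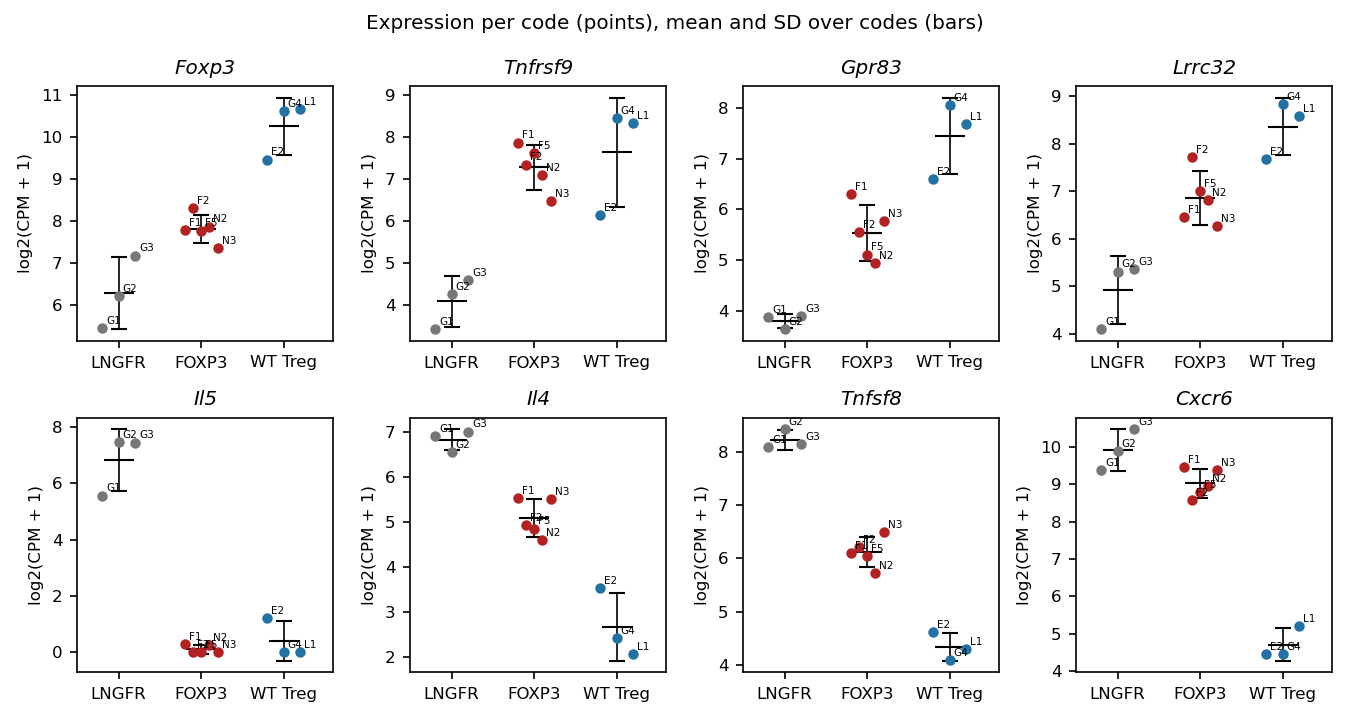
Expression of 8 named genes as log2(CPM + 1) in each code (labelled points), with the mean and SD over the codes of a group as bars. Il5 lies at 1.32 CPM or less in every FOXP3 and WT Treg code and is high in the 3 LNGFR codes (131 ± 73.9 CPM), and Foxp3 in FOXP3 (228 ± 54.3 CPM) lies between LNGFR (86.1 ± 51.5 CPM) and WT Treg (1305 ± 521 CPM).

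The second comparison, WT Treg against LNGFR, gives the difference between transferred Treg and reporter-only scurfy T cells in scurfy recipients. Donor, reporter vector and sort marker differ as well, here and in the third comparison. Their part cannot be told apart from that of the cell type. Foxp3 rose by 3.92 on the log2 scale, as given above. Among Treg genes, Gpr83 rose from 13.1 ± 1.34 (n = 3) to 188 ± 85.5 CPM (n = 3, adjusted p = 0.000937), Itgb8, an integrin chain that activates TGF-beta, from 4.46 ± 1.13 to 45.3 ± 8.67 CPM (adjusted p = 0.000797), and Lrrc32 from 31.6 ± 13.4 to 346 ± 129 CPM (adjusted p = 0.0041). Il5 had 1 count over WT Treg and 2671 over LNGFR, a ratio of CPM pooled over codes of 2200 (95% exact interval 394 to 86800). Pooling weights the deeper codes and the interval covers counting error only. The 1 count fell in E2, the shallowest code, so the ratio of mean CPM over codes (131 ± 73.9 to 0.439 ± 0.760) was 299, below that interval. Cxcr6, a chemokine receptor of effector T cells (chromosome 9, 123806475 to 123811760), fell from 1009 ± 381 to 26.1 ± 8.77 CPM, by 5.25 on the log2 scale (SE 0.47, adjusted p = 0.000198).

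Of the 34 genes higher in Treg 6 rose and 1 fell, against 11 and 2 adjusted over the list alone. Tnfrsf9 rose by 3.84 ± 0.59 (adjusted p = 0.00615) and Ikzf4, which encodes Eos, by 2.18 ± 0.37 (adjusted p = 0.0105). The one that fell was Il10, a regulatory cytokine also made by effector T cells, from 253 ± 2.47 to 29.7 ± 15.8 CPM (adjusted p = 0.00775). Il10 lies within 25 Mb of Ptprc, the gene of the CD45.1 marker, and a strain difference of the donors was not tested for it. The list median was 0.61 (camera adjusted p = 1.26e-06, and 0.495 with an estimated correlation). An exact permutation test of its mean log2 CPM per code did not pass (p = 0.3, adjusted p = 0.408). The mean log2 CPM of this list was 6.72 in E2, the code with 54.4% of its counts on the Gm10800 family, and 8.04 in G4 and 7.90 in L1. With the 3 weak libraries left out 11 members rose and 1 fell (adjusted p = 0.036 with an estimated correlation), and without codes E2, G1 and N3, 20 rose and 3 fell (adjusted p = 0.01 with an estimated correlation). Of the 11 genes lower in Treg 3 fell, and 4 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 1.26e-10; adjusted p = 0.02 with an estimated correlation). They were Tnfsf8, from 297 ± 38.9 to 19.6 ± 3.82 CPM (adjusted p = 0.000198), Cd40lg (adjusted p = 0.00136) and Tcf7, a transcription factor of naive and memory T cells (265 ± 140 to 60.6 ± 12.3 CPM, adjusted p = 0.0311).

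Of 10 effector cytokine genes 5 fell, and 7 fell and 2 rose adjusted over the list alone (median -2.94, camera adjusted p = 2.27e-11; adjusted p = 0.00105 with an estimated correlation). Il4 went from 113 ± 18.0 to 6.03 ± 3.94 CPM (adjusted p = 0.000541) and Ifng from 26.1 ± 16.5 to 1.17 ± 1.31 CPM (adjusted p = 0.0162). Of 11 T helper 2 genes 4 fell, and 7 fell and 1 rose adjusted over the list alone (median -2.18, camera adjusted p = 1.87e-11; adjusted p = 0.00105 with an estimated correlation); these were Il4, Il5, Il13 and Areg. Of 17 type 1 and cytotoxic genes 2 fell, Ifng and the granule gene Nkg7 (243 ± 182 to 43.3 ± 25.5 CPM, adjusted p = 0.0494), and 4 adjusted over the list alone (camera adjusted p = 0.000739; adjusted p = 0.0572 with an estimated correlation). Of 11 follicular helper genes 2 fell, Il4 and Tox2, and 2 adjusted over the list alone (camera adjusted p = 0.000739; adjusted p = 0.0398 with an estimated correlation). That call with an estimated correlation was lost without the 3 weak libraries (adjusted p = 0.148) and without codes E2, G1 and N3 (adjusted p = 0.417). Ier3 was again the 1 stress gene that fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0469; adjusted p = 0.772 with an estimated correlation). The camera call was lost in both added fits (adjusted p = 0.127 without the 3 weak libraries and 0.111 without codes E2, G1 and N3).

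Among 21 trafficking genes 3 rose and 1 fell, against 4 and 1 adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.258). Ccr9, a gut homing receptor, rose from 6.48 ± 3.59 to 45.3 ± 1.81 CPM (adjusted p = 0.0197), Cxcr4 from 10.7 ± 5.63 to 36.7 ± 12.7 CPM (adjusted p = 0.0323) and Gpr15 by 2.44 ± 0.55 (adjusted p = 0.0496). Without codes E2, G1 and N3, 6 trafficking genes rose and 2 fell (camera adjusted p = 0.00738, and 0.109 with an estimated correlation). Without the 3 weak libraries the list did not pass (camera adjusted p = 0.118). No cell-cycle gene passed over all genes or adjusted over the list alone, while 23 of 25 had fold changes above 0 (median 0.66, camera adjusted p = 0.0218; adjusted p = 0.772 with an estimated correlation). None rose without the 3 weak libraries (adjusted p = 0.627 with an estimated correlation). Without codes E2, G1 and N3, 15 rose (adjusted p = 0.241 with an estimated correlation). Ighm, the immunoglobulin heavy chain mu gene, was the 1 B-cell gene that rose, from 443 ± 54.0 to 2638 ± 1094 CPM (adjusted p = 0.0162), while the list median was -1.99; adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.0339; adjusted p = 0.772 with an estimated correlation). This camera call too was lost in both added fits (adjusted p = 0.122 and 0.051). No plasma-cell gene passed over all genes, and 3 fell adjusted over the list alone (median -3.75, camera adjusted p = 0.000739, and 0.309 with an estimated correlation). None passed over all genes without the 3 weak libraries. Without codes E2, G1 and N3, 2 of 5 tested plasma-cell genes fell over all genes (median -2.60, camera adjusted p = 0.000802, and 0.124 with an estimated correlation).

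In all, 97 genes were called higher and 104 lower in WT Treg than in LNGFR by edgeR, and 2290 genes had an unadjusted p under 0.05. Hpgd, which degrades prostaglandins, had 316 counts over WT Treg and none over LNGFR, at least 90.8-fold higher against a floor of 3 counts over the group. Ltb4r1, a leukotriene B4 receptor, fell from 490 ± 195 to 8.62 ± 5.65 CPM (adjusted p = 0.000783), and Ly6c2, which has a near-identical copy in Ly6c1 that can share its reads, from 229 ± 194 to 3.35 ± 2.01 CPM (adjusted p = 0.000772). Ccl24 had 1 count over WT Treg and 246 over LNGFR (pooled ratio 202, counting interval 36.0 to 8030; ratio of mean CPM 288) and Il13 2 and 194 (79.8, 21.8 to 664; 127). Foxb1 had 1 and 239 (pooled ratio 197, counting interval 35.0 to 7800), and as its 1 count was also in E2, the ratio of mean CPM was 27.9, again below the interval. Other large changes were Ttn (3.86 ± 0.54), Cep112 (3.97 ± 0.78), Slc15a2 (3.64 ± 0.78) and Rragd (3.54 ± 0.72) upward and Tspan9 (-6.67 ± 0.83) and Fcrls (-5.84 ± 1.21) downward. E2, in which long transcripts were favoured (Spearman rho 0.442 of its log2 difference from G4 and L1 with exon length), carried part of 2 of them: without it Slc15a2 had 2.72 and lost its call (adjusted p = 0.0691), and Ttn had 3.17 (adjusted p = 0.00218). Tspan9 had 4 counts over WT Treg, at 0.966 ± 1.45 against 34.1 ± 12.6 CPM in LNGFR, and the log2 ratio of these means was -5.14, smaller than the fitted value. Of 34 named genes called in this comparison, 23 lost the call without at least 1 code of the 2 groups. None changed sign, which their selection from these same codes makes likely by itself. The fold moved by over 1.5 times for 16 of the 34 and became that much smaller for 12. Beside Slc15a2, those that became smaller and lost the call were Nkg7 without G1 (-1.61), Cep112 without G3 (3.35), Fcrls without G3 (-5.20) or G4 (-5.08), Foxb1 without G4 (-6.10) or L1 (-5.85), Il13 without G4 (-5.48), and Ccl24 (-6.51) and Hpgd (9.25) without L1. Beside Ttn, those smaller and still called were Ly6c2 without G1 (-4.89), Tspan9 without G4 (-5.79) and Il5 without G4 (-9.78) or L1 (-9.55). The fold only grew for Rragd without G1 (4.89), Ccr9 without G2 (3.42), Foxp3 without G3 (4.53) and Ifng without G4 (-4.93), and Cep112 had 5.47 without G1. Without E2 it was larger for Il5 (-13.01), Foxb1 (-9.6), Tspan9 (-7.73) and Hpgd (10.48), and without G4 for Ccl24 (-9.68), all still called. Fcrls (-7.33) and Il13 (-9.23) had larger folds without L1 and lost the call. Without the 3 weak libraries the counts were 162 and 156, and without codes E2, G1 and N3 615 and 510, among which 199 of the 201 calls were kept with their sign. Leaving out 1 code gave 10 (without L1) to 147 (without E2) higher and 27 (without L1) to 157 (without N3) lower. With no scaling beyond the library total, 64 were higher and 113 lower, and DESeq2 called 402 and 364.

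**Figure D3:**
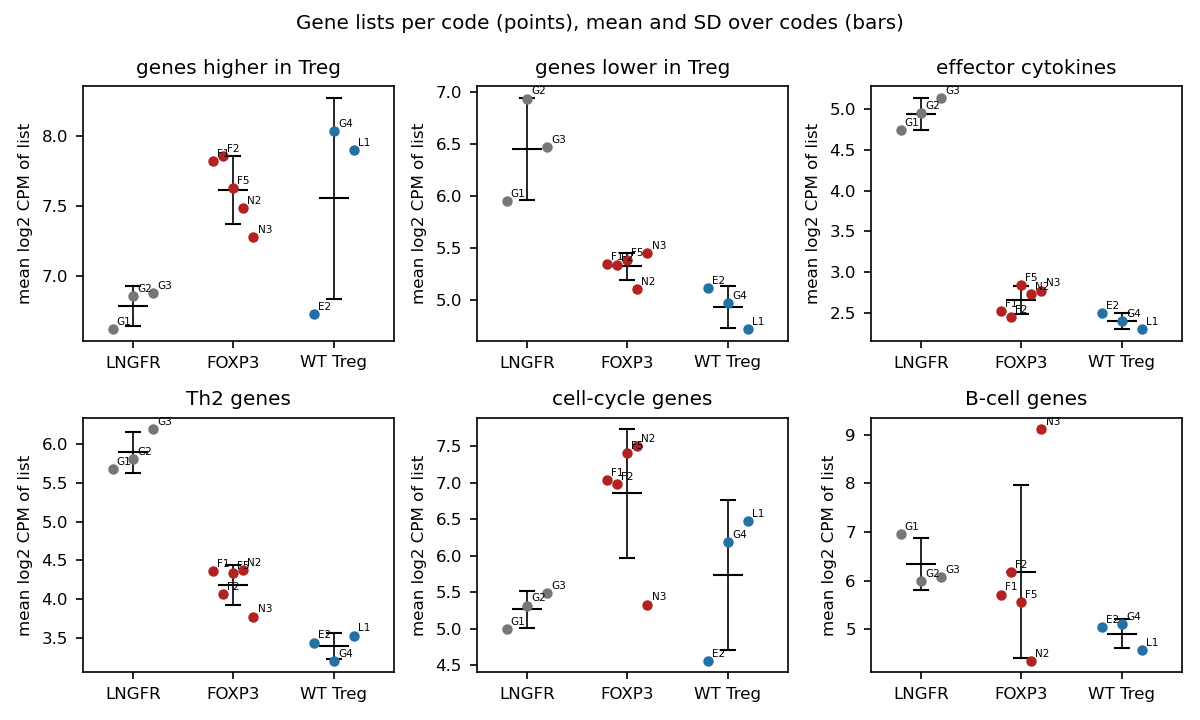
Mean log2 CPM of 6 gene lists in each code (labelled points), with the mean and SD over the codes of a group as bars. Genes lower in Treg, effector cytokines and T helper 2 genes lie lower in every FOXP3 and WT Treg code than in every LNGFR code, N3 lies apart from the other FOXP3 codes in cell-cycle genes (5.33 against 6.98 to 7.51), and E2 lies apart from G4 and L1 in genes higher in Treg (6.72 against 8.04 and 7.90).

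The third comparison, FOXP3 against WT Treg, asks how far cells with the FOXP3 vector still differed from wild-type Treg. Cxcr6 stayed 20.2-fold higher in FOXP3, at 537 ± 144 CPM (n = 5) against 26.1 ± 8.77 CPM (n = 3), a log2 fold change of 4.34 ± 0.44 (adjusted p = 0.000802). Il4 was 34.0 ± 10.1 against 6.03 ± 3.94 CPM (adjusted p = 0.0154) and Tnfsf8 69.4 ± 13.4 against 19.6 ± 3.82 CPM (adjusted p = 0.0154), both between the LNGFR and WT Treg levels. Foxp3, Gpr83 and Itgb8 were lower in FOXP3. Gpr83 stood at 48.2 ± 19.2 against 188 ± 85.5 CPM (log2 fold change -1.98 ± 0.36, adjusted p = 0.036) and Itgb8 at 13.2 ± 4.91 against 45.3 ± 8.67 CPM (-1.75 ± 0.30, adjusted p = 0.0275). Ctse, the protease cathepsin E (chromosome 1, 131638306 to 131675505), stood at 46.5 ± 7.06 against 367 ± 146 CPM (adjusted p = 0.00247).

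Among other genes higher in FOXP3 were Ltb4r1 (113 ± 54.8 against 8.62 ± 5.65 CPM, adjusted p = 0.0192), Cysltr1, a cysteinyl leukotriene receptor (115 ± 22.2 against 16.2 ± 11.6 CPM, adjusted p = 0.0192), and Ccr1 (62.9 ± 15.5 against 6.14 ± 1.45 CPM, adjusted p = 0.00193). Of the 34 genes higher in Treg 2 fell and none rose, against 5 that fell and 1 that rose adjusted over the list alone. Over all genes, 1 fell without the 3 weak libraries and 10 fell without codes E2, G1 and N3, and none rose in either fit. The list median was -0.04 (camera adjusted p = 0.719), and it was -0.30 without the 3 weak libraries (camera adjusted p = 0.000389; adjusted p = 0.215 with an estimated correlation) and -0.32 without codes E2, G1 and N3 (camera adjusted p = 0.000177; adjusted p = 0.209 with an estimated correlation). Il10 stood at 157 ± 60.2 against 29.7 ± 15.8 CPM (adjusted p = 0.0522). Of the 11 genes lower in Treg 1 rose, Tnfsf8, and 3 rose and 1 fell adjusted over the list alone (median 0.41, camera adjusted p = 0.0184; adjusted p = 0.48 with an estimated correlation).

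Il4 was the 1 member that rose among 10 effector cytokine genes (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.346), among 11 T helper 2 genes (2 rose adjusted over the list alone, camera adjusted p = 0.00482; adjusted p = 0.121 with an estimated correlation) and among 11 follicular helper genes (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.635). None of 17 type 1 and cytotoxic genes passed and 4 rose adjusted over the list alone (camera adjusted p = 0.00057; adjusted p = 0.121 with an estimated correlation). Nkg7 stood at 169 ± 30.9 against 43.3 ± 25.5 CPM (adjusted p = 0.0933). All 25 cell-cycle genes had fold changes above 0 and none passed over all genes or adjusted over the list alone (median 0.95, camera adjusted p = 2.21e-08; adjusted p = 0.594 with an estimated correlation); none rose without the 3 weak libraries (adjusted p = 0.702 with an estimated correlation), and without codes E2, G1 and N3, 17 rose (adjusted p = 0.209 with an estimated correlation), a count with the same dependence on the choice of N3. Among 21 trafficking genes Cxcr6 rose and Cxcr4 fell (8.75 ± 1.46 against 36.7 ± 12.7 CPM, adjusted p = 0.0168), against 2 and 2 adjusted over the list alone (camera adjusted p = 0.123). None of 12 stress genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.635). B-cell genes had a median of 2.77 and plasma-cell genes 2.23, with no member past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0133 and 0.166; adjusted p = 0.756 for both with an estimated correlation). Without codes E2, G1 and N3 these medians were 0.90 and 0.34, and the B-cell camera call was lost (adjusted p = 0.237). N3 held the B-cell RNA described above.

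In all, edgeR called 21 genes higher and 19 lower in FOXP3 than in WT Treg, and 2547 had an unadjusted p under 0.05. Other large changes were Msc (5.03 ± 0.73), Fcgrt (3.71 ± 0.59) and Fam20a (3.29 ± 0.50) upward and Arrdc4 (-3.06 ± 0.44), Ppm1l (-3.03 ± 0.44), Rnf187 (-2.45 ± 0.40), Cpq (-2.43 ± 0.24) and Ift80 (-2.24 ± 0.34) downward. Pltp had 4.17 ± 0.78, a value that N3 carried in part: that code held 155 CPM and the other FOXP3 codes 20.7 to 33.1, and without N3 the Pltp log2 fold change was 3.23 (adjusted p = 0.00678). Without the 3 weak libraries the counts were 30 and 36, with 31 of the 40 calls kept, and without codes E2, G1 and N3 they were 565 and 525, with all 40 kept. Leaving out 1 code gave 3 (without L1) to 67 (without G1) higher and 1 (without L1) to 1168 (without G4) lower. Of 20 named genes called in this comparison, 17 lost the call without at least 1 code of the 2 groups. None changed sign, which their selection from these same codes makes likely by itself. Without L1 the fold was over 1.5 times larger for Msc (5.78), Pltp (4.78) and Fam20a (4.03), and all 3 lost the call (adjusted p = 0.0557). DESeq2 called 215 higher and 896 lower, and with no scaling beyond the library total 20 were higher and 11 lower.

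The changes of FOXP3 and WT Treg against LNGFR were then set side by side. Of the 201 genes called in WT Treg, 192 (95.5%) had the same sign in FOXP3, 49 were also called there, and 182 (90.5%) lay between their LNGFR and WT Treg levels in FOXP3, with a median of 53.0% of the WT Treg change. These genes were picked for their distance from the same LNGFR codes, which by itself favours the same sign. Sets were therefore simulated, after the result was seen, with FOXP3 unchanged from LNGFR and the called genes at their measured WT Treg differences. Over 20 such sets a mean of 147 genes were called in WT Treg, 56.0% of them with the same sign in FOXP3 (47.0% to 63.8%), 55.8% between, with a median of 2.15% of the WT Treg change. With those log2 differences scaled by 0.5, a mean of 10.6 genes were called and 68.5% had the same sign (40.0% to 100%), too few genes to compare. Called in both were 14 genes that rose and 35 that fell, and none was called with opposite signs. Independent lists of these sizes would share 0.163 and 0.39 genes, which leaves out the shared controls. Simulated sets keep the sharing of these controls and leave out the effects. Their genes were drawn independently, so a deviation of a whole LNGFR code, as in G1, is not in them. Their ranges may therefore be too narrow for what shared controls alone can give. Sets with all 3 groups unchanged shared none but called at most 1 gene, and in those with FOXP3 alone unchanged none of the WT Treg calls was also called in FOXP3. Across all 15462 genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.26 and Spearman rho = 0.33, against 0.55 and 0.51 in 20 simulated sets with all 3 groups unchanged. The covariance was 0.269 against 0.298 simulated (0.269 to 0.315 over the 20), so no shared change was measurable over all genes with all codes in. Without the 3 weak libraries the covariance was 0.688 against 0.221 simulated (0.202 to 0.238), and r was 0.67. The correlation changed sign without WT Treg code G4 (-0.06) or L1 (-0.07), each of which left E2 as 1 of 2 WT Treg codes. Both comparisons use the same 3 LNGFR codes, which are too few to split into groups of 2, and part of the overlap may come from them.

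**Figure D4:**
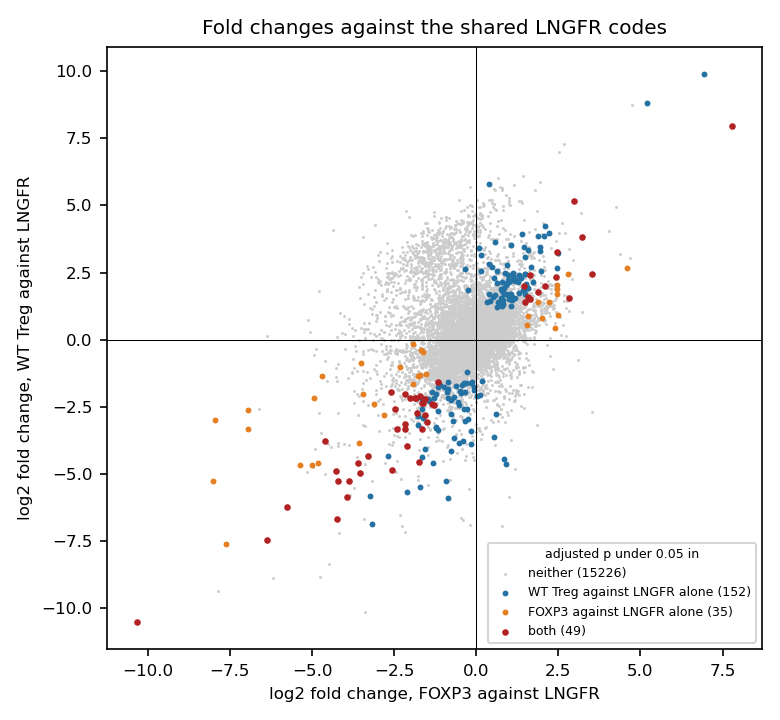
Log2 fold change of 15462 genes in WT Treg against LNGFR (vertical axis) by that in FOXP3 against LNGFR (horizontal axis), coloured by the comparisons in which the adjusted p was under 0.05. The 49 genes called in both lie toward the lower left and upper right, 35 called in FOXP3 alone and 152 in WT Treg alone are marked, and the shared LNGFR codes add a positive relation by themselves.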

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

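The tests of the FOXP3 code N3 for B-cell RNA and for dilution, of transcript length in G1, and of gene positions near Ptprc were chosen only after the result was seen, and the second setting of the Ptprc test was set beside it after its first value was seen.

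Among 108 quantities measured in the 5 FOXP3 codes, 11 had a code whose gap to its nearest neighbour was over 0.71 of the group's range. Of the 11, 7 were in N3. Chance would give about 5.4 for independent, normally distributed quantities. These are mostly CPM of single genes, which are skewed, and lists that share members, so chance can give more. The 7 of N3 come from 1 code and are not separate observations. The mean log2 CPM of the cell-cycle list was 5.33 in N3 and 6.98 to 7.51 in the others. N3 was also alone at 25.7 CPM of Prf1 (12.6 to 15.8 elsewhere), 11.1 CPM of Slc15a2 (1.76 to 3.76), 2.72 CPM of Tspan9 (1.45 to 1.68), 9.91 CPM of Fcrls (1.04 to 1.83), 75.5 CPM of Bach2 (8.34 to 13.4) and 155 CPM of Pltp (20.7 to 33.1). Elsewhere, Hpgd was 5.87 CPM in F1 (0.623 to 2.14 in the others), Ttn 255 CPM in F2 (99.6 to 144), Ift80 38.1 CPM in F2 (13.3 to 17.6) and Msc 32.2 CPM in N2 (10.1 to 15.0).

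For N3, 12 of the 12 tested B-cell genes were higher than in each other FOXP3 code, with a median log2 difference of 4.03 and Cd79a at 994 CPM, so RNA from B cells that passed the LNGFR sort is a candidate source of these transcripts. Dilution by that RNA as the whole cause of the lower cell-cycle genes is argued against: their median was -1.87 on the log2 scale, and that of the T-cell list, which dilution would lower as much, was -0.56 (SD 0.15 over genes). Loss of long transcripts in N3 is argued against too, since the log2 difference rose with exon length (Spearman rho 0.215 across 8767 genes). A biological difference between the cells of N3 and the other codes stays open, as untested.

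LNGFR code G1 stood apart from G2 and G3. B-cell RNA as the whole cause is argued against, because 8.51% of genes were more than 4-fold lower in G1 than in the mean of G2 and G3, against 0.148% between G2 and G3, and the T-cell list was not lower (median log2 difference 0.65). Loss of long transcripts may be part of it and cannot be told apart from other faults of the libraries of G1: the difference fell with exon length (rho -0.286, against 0.088 for G2 over G3) but did not reach the bound set for it. The first library of G1, not one of the weak libraries, held 2776945 of the 3109515 counts of G1, so the summed values rest mainly on it. Among all codes G1 also had the lowest levels of the Y-linked genes Ddx3y (15.8 CPM) and Eif2s3y (29.6 CPM). The design gives no biological group to G1, so no biological explanation was tested.

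Ctse lies within 25 Mb of Ptprc, the gene of the CD45.1 marker that the donors of WT Treg carried, and a strain difference around it is a candidate explanation for its higher level there. Of 39 genes called between FOXP3 and WT Treg that have a position, 4 (Ctse, Cxcr4, Yod1 and Acbd6) lay in that window, against 253 of 15112 other genes, an odds ratio of 6.71 (Fisher's exact two-sided p = 0.00417, 95% interval 1.72 to 19.0). That first value alone met the bound set for strain, but Ctse, which prompted the test, counts among the 4. Without codes E2, G1 and N3, a setting added afterwards, the window held 24 of 1077 called genes (odds ratio 1.37, 95% interval 0.858 to 2.11, exact p = 0.139), so strain and the difference between the cells cannot be told apart for these 4 genes. A difference between Treg and converted cells stays open, as untested. Il10 lies in the same window, and Il10 and Cxcr4 were also called in WT Treg against LNGFR. The window was not tested in that comparison, so strain stays open there too.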

How the results depend on the processing

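The fits without the 3 weak libraries, without codes E2, G1 and N3, with the exon length trend removed and with no scaling beyond the library total were chosen only after the result was seen, while the other settings and the splits were planned.

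The counts of called genes depended strongly on the setting, and where not stated the cause was not tested. With all codes they were 26 higher and 58 lower for FOXP3 against LNGFR, 97 and 104 for WT Treg against LNGFR and 21 and 19 for FOXP3 against WT Treg; the values below follow that order. DESeq2 gave 223 and 187, 402 and 364, 215 and 896. No filter gave 185 and 144, 716 and 284, 404 and 3211. Fits of only the 2 groups compared gave 49 and 135, 18 and 40, 52 and 83. Each library as a replicate gave 362 and 419, 399 and 392, 303 and 644, and limma voom with the code as a random effect 243 and 229, 303 and 242, 113 and 274. limma voom with quality weights gave 517 and 516, 441 and 429, 345 and 704. The libraries numbered 1 gave 42 and 70, 135 and 120, 32 and 45, and those numbered 2 gave 6 and 33, 18 and 32, 5 and 5. RLE size factors gave 18 and 52, 108 and 108, 29 and 34. FOXP3 codes that start with F gave 53 and 41 against LNGFR and 6 and 2 against WT Treg. Codes that start with N, which leave 2 FOXP3 codes, gave 0 and 0 against both by edgeR, with 483 and 950 genes at an unadjusted p under 0.05; DESeq2 and limma were not run on that subset.

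Without the 3 weak libraries the counts were 101 and 149, 162 and 156, 30 and 36, and without codes E2, G1 and N3, where fewer codes remain, 971 and 594, 615 and 510, 565 and 525. Removing the exon length trend gave 37 and 72, 109 and 131, 44 and 34. No scaling beyond the library total gave 20 and 64, 64 and 113, 20 and 11, and moved the median of all genes from 0.08 to -0.04 for WT Treg against LNGFR and from 0.01 to 0.11 for FOXP3 against WT Treg. No called named gene changed sign in any setting. These genes were picked past the threshold from the same codes, the largest changes also for no overlap of codes. That choice by itself makes a change of sign unlikely, so it does not speak for stability.

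Leaving out 1 code gave 1 (without G2) to 161 (without N3) higher and 12 (without G3) to 152 (without E2) lower for FOXP3 against LNGFR. The counts there were 7 and 22 without F1, 5 and 22 without F2, 6 and 24 without F5, 8 and 26 without N2, 161 and 112 without N3, 16 and 42 without G1, 1 and 13 without G2, 3 and 12 without G3, 94 and 152 without E2, 18 and 40 without G4 and 11 and 28 without L1. For WT Treg against LNGFR the range was 10 (without L1) to 147 (without E2) higher and 27 (without L1) to 157 (without N3) lower, with 60 higher without F5, 12 and 38 without G2, 21 and 45 without G3 and 26 and 33 without G4. For FOXP3 against WT Treg it was 3 (without L1) to 67 (without G1) higher and 1 (without L1) to 1168 (without G4) lower, with 9 and 8 without F1, 10 and 5 without F5, 10 and 7 without N2, 67 and 81 without G1, 7 lower without G2, 32 and 34 without E2 and 62 higher without G4.

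The library numbers did not pair the samples: the difference between libraries 1 and 2 correlated between codes at a median of 0.001 (-0.033 to 0.121 over 55 pairs). With the number as a replicate block and each library as a replicate, the counts were 342 and 379, 368 and 354, 285 and 618.

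The list of genes higher in Treg had a median of 0.75 for FOXP3 against LNGFR and 0.61 for WT Treg against LNGFR. On these same fits it lost its call with an estimated correlation (adjusted p = 0.253 and 0.495) and with fry (0.0857 and 0.149). Without 1 code the medians were 0.59 to 1.08 and 0.38 to 0.98. Genes lower in Treg kept their calls in both, with medians of -1.53 to -1.06 and -1.83 to -0.60 without 1 code. For FOXP3 against WT Treg the list of genes higher in Treg was -0.04 with all codes, 0.12 with no filter, -0.30 without the 3 weak libraries (adjusted p = 0.215 with an estimated correlation) and -0.32 without codes E2, G1 and N3. Without 1 code it ran from -0.30 (without E2) to 0.26 (without G4), with 0.04 without G2, 0.01 without G3 and 0.15 without L1. Genes lower in Treg had 0.41 there and lost the call with an estimated correlation (adjusted p = 0.48), with fry (0.147) and without L1 (0.50, adjusted p = 0.134), within a range of 0.29 to 0.66 without 1 code; the cause was not tested.

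The camera test changed direction for other lists, here with the list median in that setting. For FOXP3 against LNGFR these were type 1 and cytotoxic genes (0.22 with no filter, 0.21 without G1, 0.32 without codes E2, G1 and N3; -0.34 to 0.21 without 1 code), respiration genes (-0.27 without the 3 weak libraries) and B-cell genes (-0.74 without N3, -0.62 without codes E2, G1 and N3; -0.74 to 1.49 without 1 code). For WT Treg against LNGFR they were glycolysis (-0.67 without G4 to 0.0137 without E2) and respiration (0.0915 without codes E2, G1 and N3). For FOXP3 against WT Treg they were follicular helper genes (-0.30 without codes E2, G1 and N3) and stress genes (0.19 with no filter, 0.13 without F2, 0.56 without L1; -0.29 to 0.56 without 1 code). With all codes the median and the test differed in sign for respiration genes in the first comparison (median -0.04, mean 0.04, test upward) and follicular helper genes in the third (median -0.02, mean -0.26, test upward). The correlation of the 2 sets of changes was -0.0616 without G4, -0.0735 without L1 and 0.61 without E2.

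Of the 56 splits of the codes 1 gave as many called genes as FOXP3 against LNGFR (84, highest other 0) and 1 as many as FOXP3 against WT Treg (40, highest other 0), a share of 0.0179 for each. This share is under the bound of 0.05 set for chance, but it was not adjusted over the 3 comparisons. It is the smallest that 56 splits allow. With no call in any other split it would be the same for a single called gene, so it does not speak for the number of genes. For WT Treg against LNGFR 1 of 10 splits did (201, highest other 0), and 10 splits are too few for a share under 0.05. In E2 1 count of Il5 stood for 1.32 CPM, so a lower level could not be measured in that code.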

Other observations

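The fit without codes E2, G1 and N3 and the tests given here were chosen only after the result was seen, while the tests of the lists were planned.

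The difference in energy metabolism genes between FOXP3 and WT Treg depended in part on code E2. The mean log2 CPM of the respiration list was 5.95 in E2, 7.53 in G4 and 7.48 in L1, and that of glycolysis 6.13, 7.60 and 7.66, and the exact permutation tests did not pass (adjusted p = 0.195 and 0.19). All 20 genes of respiration had fold changes above 0 (median 0.50) and 12 of 13 glycolysis genes did (median 0.59), with no member past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.000237 for each; adjusted p = 0.594 for each with an estimated correlation). Without the 3 weak libraries the respiration median was 0.15 and its call was lost (camera adjusted p = 0.322), and the glycolysis median was 0.31 (camera adjusted p = 0.0434; adjusted p = 0.702 with an estimated correlation). The medians were 0.23 and 0.38 without codes E2, G1 and N3 (camera adjusted p = 0.00699 and 0.000548; adjusted p = 0.549 for both with an estimated correlation). Between WT Treg and LNGFR the respiration list had a median of -0.53 (camera adjusted p = 0.00631; adjusted p = 0.772 with an estimated correlation) and glycolysis -0.37 (camera adjusted p = 0.0684). That respiration call was lost without the 3 weak libraries (camera adjusted p = 0.467) and without codes E2, G1 and N3 (median 0.09, camera adjusted p = 0.529). Between FOXP3 and LNGFR the respiration and glycolysis medians were -0.04 and 0.37 (camera adjusted p = 0.687 and 0.0792). These last became 0.36 and 0.42 without codes E2, G1 and N3, with 8 and 2 members that rose (camera adjusted p = 0.000383 and 0.0315; adjusted p = 0.36 and 0.684 with an estimated correlation).

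Without codes E2, G1 and N3 other genes passed between FOXP3 and LNGFR that had missed the threshold with all codes. Ikzf2 then had a log2 fold change of 1.37 ± 0.19 (n = 4 and 2, edgeR adjusted p = 0.000906, against 0.109 with all codes), Il2ra, the IL-2 receptor alpha chain chosen after its values were seen, 1.09 ± 0.12 (adjusted p = 0.000117, against 0.222 with all codes), and Mki67, a marker of cycling cells that is low in N3 (50.4 CPM), 2.01 ± 0.24 (adjusted p = 0.000392). These values rest on leaving out codes picked from the data, and for Mki67 the choice of N3 is not independent of its level. In that fit 1045 of 1125 genes called in WT Treg (92.9%) had the same sign in FOXP3, and 860 (76.4%) lay between the LNGFR and WT Treg levels, with a median of 57.9% of the WT Treg change. In simulated sets with FOXP3 unchanged these were 57.6%, 57.4% and 2.74% with the called genes at their measured WT Treg differences, and 68.0%, 67.9% and 8.28% with the log2 differences scaled by 0.5. The covariance of the fold changes was 0.656 against 0.156 in simulated unchanged groups.

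Y-linked transcripts were present in all 11 codes, with Ddx3y at 15.8 to 84.8 CPM and Uty at 18.5 to 48.0 CPM. Xist stood at 61.9 CPM in E2 and at 3.36 CPM or less in the other 10 codes, and the cause was not tested. Long transcripts were favoured in E2 (Spearman rho 0.442 with exon length), and the Y-linked Kdm5d was also highest there at 76.3 CPM (13.8 to 47.3 CPM elsewhere), so a fault of the weak library and RNA of female cells both stay open. Mitochondrial genes took 0.715% of the counts in the second library of G1 and 2.47% in the first.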
